A study of Mus musculus with 4 samples.

How the data were processed

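Single-cell RNA sequencing was carried out on mouse small-intestinal crypts, the pits of the epithelium that hold its stem cells and Paneth cells. Per the labels' protocols, crypts were released with 10 mM EDTA, passed through a 70 µm strainer and made into libraries with a 10x Genomics 3′ kit of version 2. The series design states that epithelial cells were taken from mice before and after sleep deprivation. The labels give 4 libraries in 2 groups, 0D with replicates 1 and 2 and 2D with replicates 1 and 2, and do not spell out what D stands for. The libraries are called 0D-1, 0D-2, 2D-1 and 2D-2 here. The labels do not say whether each library came from a separate animal.

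Each library has a matrix of raw UMI counts deposited by the authors, as whole numbers per gene and cell barcode for 32285 genes. UMIs, unique molecular identifiers, count captured transcript molecules after PCR copies are merged. The sources differ on the counting program. Per the submitters' processing notes it was Cell Ranger 2.1.1 with the mouse build mm10, and per the file headers the matrices were written by cellranger 7.0.0. Whether intron reads were counted and which gene annotation was used are not given in the sources used here. Intron counting would change counts per gene, and the same choice is assumed for all 4 libraries. The smallest deposited barcode had 500 UMIs in each library, so the barcodes had been filtered before deposit.

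Deposited barcodes numbered 9561, 9363, 9703 and 10024 in 0D-1, 0D-2, 2D-1 and 2D-2, with 117885126, 115715547, 118874594 and 96124977 UMIs. Cells with at least 500 detected genes and at most 20% mitochondrial UMIs were kept. That left 7586, 7132, 7025 and 7988 cells, 29731 in all, with 113758758, 110817632, 110587001 and 93090534 UMIs. Doublets, droplets with more than 1 cell, were scored per library with Scrublet through scanpy at an expected share of 0.08. Its automatic threshold called 624, 367 and 521 cells in 0D-1, 0D-2 and 2D-1 and 0 in 2D-2. It was therefore taken not to have worked in 2D-2 (working minimum 0.5% of cells). The rule fixed beforehand was to keep all cells where Scrublet failed. It did not say whether a failure in 1 library covers the others. Here all cells were kept in the 4 libraries alike. Leaving out the automatic calls, which follows the other reading of that rule, was run as an alternative. So was leaving out cells above 1 common score in every library (534, 416, 560 and 640 cells). That last alternative was chosen after seeing the data.

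Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen across libraries, and 30 principal components with 15 neighbours gave 25 Leiden clusters at resolution 1 (seed 1). CPM are UMI counts scaled by a total, for naming that of the cluster and elsewhere that of the summed library. Each class was scored in each cluster by the mean log2 ratio of its markers to all other cells, with a prior of 10 CPM. The cluster was named X-like after the highest score if at least 3 of that class's markers reached 10 CPM and 2-fold. It stayed unnamed if another class had more markers among its 10 leading genes of at least 50 CPM. So did a shallow cluster with no marker of its class among them. Names of cell classes were rebuilt in this way, since no deposited annotation was used here. They gave 7 epithelial classes, 1 small B and plasma cell cluster and 1 unnamed cluster of 994 cells with a median doublet score of 0.293 and under 3 markers. No batch correction was applied. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

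Cells are not replicates, so raw UMIs were summed per library and class, and the sums of 2 against 2 libraries were compared. The test was edgeR's quasi-likelihood test (filterByExpr, TMM scaling, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). Each class had at least 20 cells in every library. The difference of the change between stem-like and enterocyte-like cells was tested as a class-by-group term with library as a block. For 34 gene lists (cell markers, cell cycle, signalling, stress, immune and metabolic groups), limma's camera with a preset inter-gene correlation of 0.01 compared members with all other genes. Adjustment was over the lists with at least 3 tested members. The same test with the correlation estimated per list, and fry, were alternatives. Of all list symbols, 1 (Pla2g2a) matched no gene, and Ctgf and Cyr61 were matched through synonyms as Ccn2 and Ccn1. Shares of each class among epithelial cells were compared with a two-sided exact permutation test over libraries, whose smallest possible p with 2 against 2 is 0.333. Intervals on single-library shares are exact binomial (Clopper-Pearson) at 95% and cover counting error only.

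The gene lists, markers, tests, thresholds and the rule for naming genes were fixed before the data were examined. By that rule the text names, per comparison, the genes past the threshold with a mean log2 CPM of at least 4 whose libraries did not overlap between groups, up to 10 each way (5 each way for goblet-like, enteroendocrine-like and tuft-like cells and for the difference between classes). Where fewer than 5 genes passed, the 5 with the smallest p are given as not passing. Of each list described, the 2 to 4 members with the smallest p are named. Unnamed loci are counted but not named, except the locus Gm42418, which was chosen after its values were seen and is named in the closing part. Levels are CPM with TMM scaling, as mean ± SD of 2 libraries. Coordinates are of GRCm38 (mm10) in the GENCODE vM21 annotation, joined by gene identifier; 363 of 363 identifiers matched. The alpha-defensin genes (Defa) form a multigene family of near-identical copies, so how reads were split between its members is uncertain. One gene that this rule selects is not reported here.

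Alternatives were RLE scaling, DESeq2, no low-count filter, at most 10% mitochondrial UMIs, both doublet removals, Leiden resolution 0.5, the replicate number as a block, and leaving out each library in turn. The class-by-group term was not refitted without single libraries. The test was tested on simulated counts with 200 changed genes, drawn at each class's depth. The spread over the 4 libraries was fitted as a trend on expression level. Simulated genes of like level thus had the same spread, which real genes do not, so the test may recover fewer changes in the real data. For all cells it recovered 79% of 2-fold and 98% of 4-fold changes, for stem-like cells 82% and 96%, for transit-amplifying-like cells 81% and 98%, for enterocyte-like cells 67% and 96%, for Paneth-like cells 65% and 94%, for goblet-like cells 68% and 96%, for enteroendocrine-like cells 82% and 100%, and for tuft-like cells 60% and 94%. In these simulations camera with the preset correlation called the raised list in every comparison and 0 of 33 unchanged lists, and with an estimated correlation it called neither. Simulated genes varied independently of each other, so these runs could not show how the preset correlation performs on lists of genes that vary together.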

Results

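Transcripts of mouse small-intestinal crypt cells were counted in 4 libraries, 2 labelled 0D and 2 labelled 2D. These groups are read here as before and after sleep deprivation, which the labels do not spell out. After filtering, 0D-1, 0D-2, 2D-1 and 2D-2 held 7586, 7132, 7025 and 7988 cells, with medians of 12115.5, 13340.5, 11117 and 9247.5 UMIs and 2996, 3165, 2975 and 2468 genes per cell. The median mitochondrial share of UMIs was 4.48%, 3.96%, 6.25% and 3.71%. Before filtering, 13.6% of the barcodes of 2D-1 were left out for a mitochondrial share over 20%, against 5.79% in 2D-2. Nothing in the labels says that the libraries came from separate animals, so all p-values measure only the spread between these libraries, which may be technical. The 0D pair lay close together in all cells (root mean square log2 difference 0.113), while the 2D pair lay 0.344 apart, about as far as the 0D and 2D libraries from each other (0.302 to 0.355).

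The first question was which kinds of crypt cell were more or less frequent after sleep deprivation. Stem-like cells, which renew the epithelium and were named from markers such as Lgr5 and Olfm4, made up 15.2% ± 2.05 of epithelial cells in 0D and 7.36% ± 1.04 in 2D (SD, n = 2). Of these cells, 1620 lay in a cluster that scored 1.698 for stem and 1.661 for transit-amplifying markers, and at Leiden resolution 0.5 the stem-like shares were 9.28% and 3.83%. Transit-amplifying-like cells, their dividing progeny, made up 17.3% ± 0.404 and 11.6% ± 2.32 (SD, n = 2). Paneth-like cells, which secrete antimicrobial peptides at the crypt base, made up 7.83% ± 1.10 and 15.9% ± 5.51 (SD, n = 2). Mucus-secreting goblet-like cells made up 30.5% ± 2.07 and 37.2% ± 1.87, and hormone-producing enteroendocrine-like cells 8.0% ± 0.784 and 11.2% ± 0.521 (SD, n = 2). Each of these 5 classes had both 2D libraries on one side of both 0D libraries, and chemosensory tuft-like cells (3.61% ± 0.572 and 4.81% ± 1.11, SD, n = 2) had 4.02% in both 0D-2 and 2D-1. With at most 10% mitochondrial UMIs per cell this failed for goblet-like cells, at 30.7%, 33.9%, 27.3% and 39.0% in 0D-1, 0D-2, 2D-1 and 2D-2, and their difference was 0.855 percentage points in place of 6.77. Absorptive enterocyte-like cells overlapped between groups, at 13.4% ± 0.777 and 9.28% ± 5.86 (SD, n = 2).

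**Figure D1:**
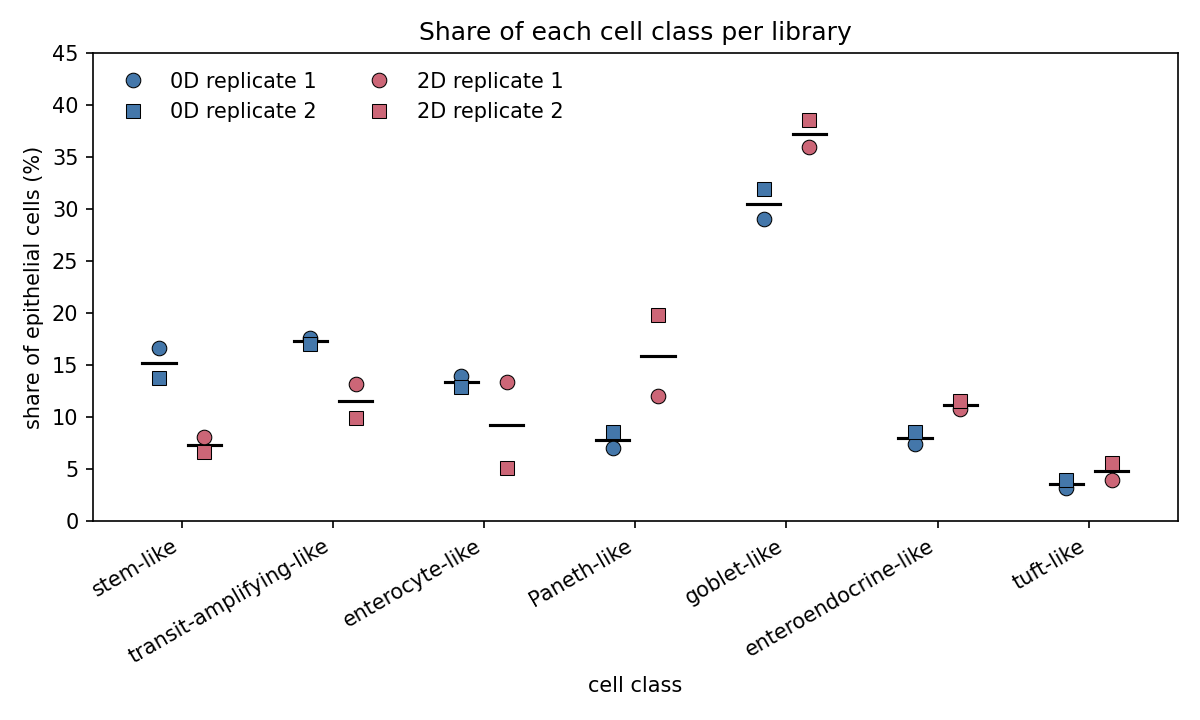
Share of epithelial cells (%) in each rebuilt cell class, with 1 point per library and a line at the mean of each group. Stem-like cells lie lower in both 2D libraries (8.10% and 6.63%) than in both 0D libraries (16.7% and 13.8%), and Paneth-like cells lie higher (12.0% and 19.8% against 7.05% and 8.61%).

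For stem-like cells the single-library shares were 16.7% (95% exact binomial interval 15.9 to 17.6), 13.8% (13.0 to 14.6), 8.10% (7.47 to 8.76) and 6.63% (6.09 to 7.20) in 0D-1, 0D-2, 2D-1 and 2D-2. For Paneth-like cells they were 7.05% (6.48 to 7.65), 8.61% (7.97 to 9.28), 12.0% (11.3 to 12.8) and 19.8% (18.9 to 20.7). In the two-sided exact permutation test over libraries, p was 0.333, the smallest this design allows, for every class but enterocyte-like cells (p = 0.667). With edgeR's quasi-likelihood test on cell numbers, 0 of 7 classes passed. The log2 ratios were -1.05 ± 0.31 (SE) for stem-like, 1.02 ± 0.34 for Paneth-like and 0.29 ± 0.11 for goblet-like cells, each with an adjusted p of 0.0565 in edgeR. These 3 classes had an unadjusted p under 0.05. Without 2D-2 the difference for Paneth-like cells was 4.20 percentage points in place of 8.10, and that for enterocyte-like cells was 0.00145 in place of -4.14 (-8.29 without 2D-1). That for tuft-like cells was 1.19 percentage points, and 0.408 without 2D-2, 1.98 without 2D-1, 0.789 without 0D-1 and 0.676 with at most 10% mitochondrial UMIs. For transit-amplifying-like cells that last setting gave -3.78 in place of -5.73. At Leiden resolution 0.5 the difference was 5.32 for Paneth-like and -8.66 for enterocyte-like cells, and with doublets at a common score left out it was -2.15 for enterocyte-like cells. The largest Paneth-like cluster in cells (1671) had a median of 35080 UMIs and another (1067 cells, 546 of them from 2D-2) had 2247, so part of this class was shallow. The remaining Paneth-like cluster (110, 127, 221 and 376 cells of 0D-1, 0D-2, 2D-1 and 2D-2) was led by Rnase1 and Retnlb, with 1 Paneth marker among its 10 leading genes, and at resolution 0.5 a cluster led by Ccl9, Retnlb and Rnase1 was named goblet-like. Clusters called goblet-like and enterocyte-like were filled unevenly. Of the 2467 cells of a goblet-like cluster led by Ddx60, Fut2, Irf7 and Ly6a, 2092 came from 2D-1, and of the 883 cells of an enterocyte-like cluster led by Ly6a, Reg3b and Isg15, 838 did. A goblet-like cluster led by the stress genes Atf3, Fos, Dusp1 and Egr1 held 589, 619, 186 and 1194 cells of 0D-1, 0D-2, 2D-1 and 2D-2.

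Over all cells together, transcripts of Paneth and enteroendocrine cells were higher in 2D and those of S phase and of absorptive cells lower. The Paneth cell marker list rose, with all 13 tested members above 0 and a median log2 change of 0.99. Mmp7, which activates alpha-defensins, was at 588 ± 94.6 CPM in 0D and 1172 ± 200 CPM in 2D (SD, n = 2), and Mptx2, a mucosal pentraxin, at 1748 ± 174 and 3269 ± 312 CPM (SD, n = 2). Enteroendocrine markers rose (15 of 16 above 0, median 0.70), with chromogranin A (Chga) at 183 ± 10.9 and 348 ± 11.1 CPM (SD, n = 2) and the transcription factor gene Neurod1 at 23.3 ± 2.99 and 48.5 ± 5.22 CPM (SD, n = 2). S phase genes fell (0 of 25 above 0, median -0.40), among them the replication licensing genes Mcm3 (log2 -0.60 ± 0.08 SE) and Mcm6 (-0.54 ± 0.07 SE). Nuclear genes of oxidative phosphorylation fell (0 of 27 above 0, median -0.26), with Cox6c at 937 ± 22.5 and 714 ± 14.0 CPM (SD, n = 2), and enterocyte markers fell (16 of 18 below 0, median -0.41), with lactase (Lct) at log2 -2.01 ± 0.20 (SE). Camera's adjusted p with the preset correlation was 1.27e-16 for Paneth, 1.33e-13 for enteroendocrine, 1.97e-13 for S phase, 7.81e-08 for oxidative phosphorylation and 5.82e-07 for enterocyte genes, and each had an adjusted p = 0.621 with an estimated correlation. The enterocyte median was -0.85 without 2D-1 and -0.24 without 2D-2.

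These sums carry the shift in cell classes as well as changes within cells. Of the 32 lists tested in all cells, 13 passed with the preset correlation, 6 higher and 7 lower, and 21 passed without 2D-1. With edgeR's quasi-likelihood test 0 of 15454 genes passed the adjusted threshold (smallest adjusted p 0.120), while 3132 had an unadjusted p under 0.05 (1726 higher, 1406 lower) and DESeq2 called 758. Leaving out 2D-1 gave 4045 genes and leaving out 2D-2 gave 1915. Adjusted over the list alone, 13 Paneth, 12 enteroendocrine and 21 S phase genes passed, against 0 over all genes. The 5 genes with the smallest p were lower in 2D and did not pass. Among them were the replication-dependent histone genes Hist1h2ab (chromosome 13, 23751126 to 23751598; log2 -1.60 ± 0.10 SE) and Hist1h4h (-1.18 ± 0.07 SE), each with an edgeR adjusted p of 0.120. The alcohol dehydrogenase gene Adh6a had a log2 value of -1.10 ± 0.08 (SE). For 55.6% of genes the ranges of the 2 groups did not overlap, against 33.3% for libraries that vary alike. These did not, as the 2D pair lay further apart than the 0D pair here (0.344 against 0.113) and in each class. A wide 2D pair falls on the same side of a close 0D pair more often, with no change common to both. The 33.3% may thus be too low a baseline here and in each class. The glucocorticoid response list, fixed for its link to stress, had 11 of 15 members above 0 (median 0.21) and did not pass (camera adjusted p 0.231, and adjusted p = 0.750 with an estimated correlation), but without 2D-1 it did (median 0.25, camera adjusted p 0.00458), with 5 members higher and 0 lower over all genes. Its members with the smallest p went both ways. Zbtb16 was at log2 1.18 ± 0.28 and Fkbp5 at 0.74 ± 0.30, while Mt1 was at -0.65 ± 0.27 (SE). Circadian clock genes rose in all cells, with 12 of 15 above 0 and a median of 0.17 (camera adjusted p 0.0432, and adjusted p = 0.621 with an estimated correlation), led by the clock repressors Nr1d2 (5.02 ± 0.146 and 9.05 ± 1.78 CPM, SD, n = 2) and Nr1d1 (7.19 ± 0.600 and 14.5 ± 4.79 CPM, SD, n = 2). The clock call was lost without 0D-2 (camera adjusted p 0.0962), without 2D-2 (0.118) and with at most 10% mitochondrial UMIs (0.0879), and 3 clock genes passed when adjusted over the list alone, against 0 over all genes. ER stress genes had all 18 members above 0 (median 0.42, camera adjusted p 4.50e-05, and adjusted p = 0.750 with an estimated correlation), a call lost without 2D-2 (median 0.14, camera adjusted p 0.0809). Immediate early and dissociation genes, which respond to handling, lay above 0 beside them (18 of 18, median 0.37, camera adjusted p 0.00569, and adjusted p = 0.750 with an estimated correlation), with Socs3 at log2 0.81 ± 0.12 and Fosb at 0.55 ± 0.21 (SE). Their median was 0.77 without 2D-1, and the call was lost without 2D-2 (median -0.13, camera adjusted p 0.0624) and with at most 10% mitochondrial UMIs (0.26, 0.122).

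Interferon response genes, which answer viral infection and type I interferon, were high in 2D-1 alone. In all cells the median over the list lay 1.75 log2 units above the 0D mean in 2D-1 and -0.10 from it in 2D-2. The master regulator Irf7 (chromosome 7, 141262706 to 141266481) was at 32.2, 32.1, 245 and 46.0 CPM in 0D-1, 0D-2, 2D-1 and 2D-2. Every one of the 7 classes showed this in 2D-1, with medians of 1.91 in stem-like, 1.93 in transit-amplifying-like, 2.21 in enterocyte-like, 1.31 in Paneth-like, 1.60 in goblet-like, 1.68 in enteroendocrine-like and 1.98 in tuft-like cells. In 2D-2 the same medians were -0.15, 0.15, 0.05, 0.01, -0.02, -0.06 and 0.36. The list passed camera with the preset correlation in all cells (adjusted p 0.0103, and adjusted p = 0.750 with an estimated correlation). Without 2D-1 its median log2 change was -0.05 there (camera adjusted p 0.938). It also passed in each class, and without 2D-1 camera's adjusted p was 0.877 in transit-amplifying-like, 0.702 in enterocyte-like, 0.258 in Paneth-like, 0.420 in goblet-like, 0.266 in enteroendocrine-like and 0.0914 in tuft-like cells, while in stem-like cells the list then lay lower in 2D (median -0.25, camera adjusted p 0.00219). With an estimated correlation it was adjusted p = 0.753, 0.736, 0.657, 0.485, 0.795, 0.457 and 0.591 in stem-like, transit-amplifying-like, enterocyte-like, Paneth-like, goblet-like, enteroendocrine-like and tuft-like cells.

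**Figure D2:**
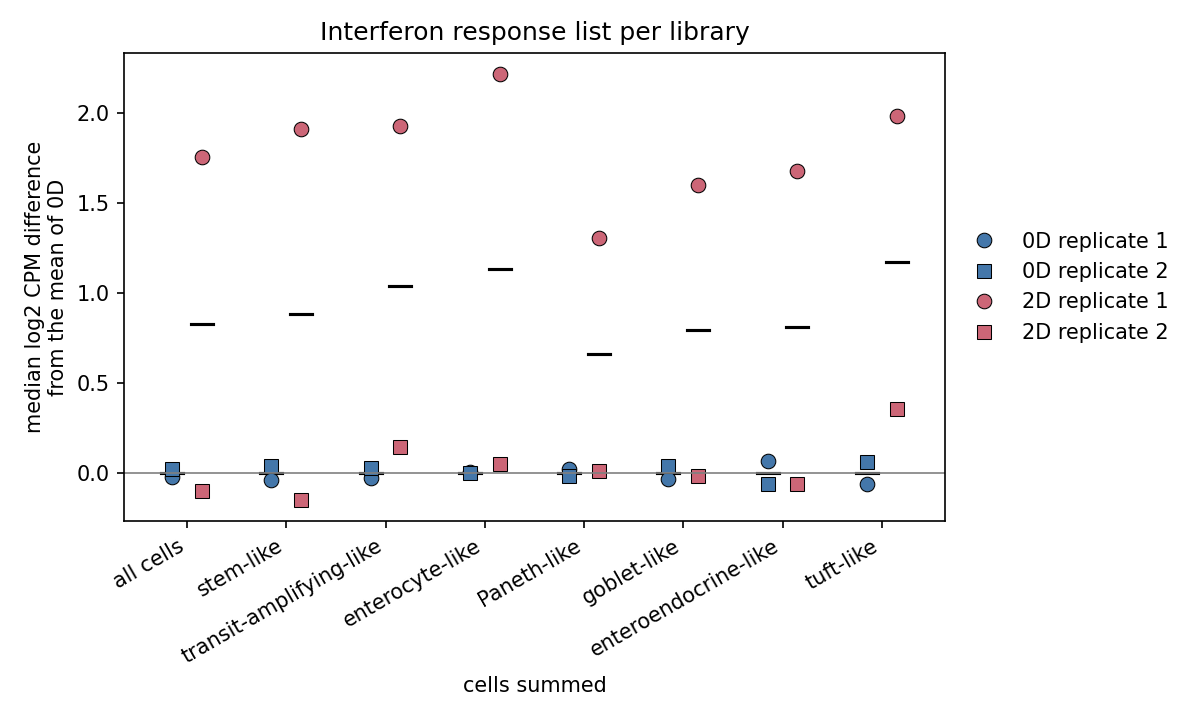
Median log2 difference of the interferon response genes from the mean of the 0D libraries, for each library (points) in all cells and in each cell class. 2D-1 lies between 1.31 and 2.21, and 2D-2 between -0.15 and 0.36.

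MHC class II genes, whose products present peptides to T cells and which crypt cells also express, were lower in 2D in every class. In all cells, all 7 members lay below 0 (median -0.93), and Cd74, the invariant chain (chromosome 18, 60803848 to 60812652), was at 521 ± 86.1 CPM in 0D and 274 ± 12.0 CPM in 2D (SD, n = 2). Enteroendocrine-like cells had a median of -1.12 (7 of 7 below 0) and tuft-like cells one of -1.08 (6 of 6 below 0). In enteroendocrine-like cells 4 members passed over all genes with edgeR, namely Cd74 (log2 -1.12 ± 0.14 SE, adjusted p 0.00481), H2-Aa (-1.31 ± 0.18 SE), H2-Eb1 (-1.22 ± 0.19 SE) and H2-Ab1 (-0.74 ± 0.10 SE), and 7 passed when adjusted over the list alone. In tuft-like cells 2 members passed, Cd74 (log2 -1.10 ± 0.16 SE, edgeR adjusted p 0.0112) and H2-Eb1 (-1.60 ± 0.28 SE, edgeR adjusted p 0.0306), and 5 passed when adjusted over the list alone. The medians were -0.87 in transit-amplifying-like, -0.93 in Paneth-like, -0.98 in enterocyte-like, -0.61 in goblet-like and -0.38 in stem-like cells. With the preset correlation, camera's adjusted p was 9.40e-09 in all cells, 1.70e-25 in enteroendocrine-like, 4.32e-14 in tuft-like, 3.67e-08 in transit-amplifying-like, 5.93e-19 in Paneth-like, 3.45e-05 in enterocyte-like, 0.000120 in goblet-like and 0.00800 in stem-like cells. In the same order it was adjusted p = 0.621, 0.280, 0.591, 0.664, 0.485, 0.657, 0.787 and 0.753 with an estimated correlation. The stem-like call was lost without 0D-2 (median -0.09, camera adjusted p 0.360), without 2D-1 (-0.01, 0.819) and at Leiden resolution 0.5 (-0.18, 0.0716), and the goblet-like call without 0D-2 (-0.35, 0.0592). The stem-like median was -0.59 without 0D-1 and -0.77 without 2D-2, the goblet-like median -0.95 without 0D-1. In enterocyte-like cells it was -0.58 without 0D-2, -0.45 without 2D-1 and -1.60 without 2D-2. H2-Eb1 in enteroendocrine-like cells missed the threshold without 0D-1 (log2 -1.17, edgeR adjusted p 0.0860), and without 0D-2 so did Cd74 (-0.99, 0.130) and H2-Eb1 (-1.13, 0.197) in tuft-like cells. Leaving out doublet calls, which also changed the clusters, ended some of these calls. The automatic calls came from the libraries other than 2D-2, and without them a cluster of 297 cells led by Neurog3 was no longer named enteroendocrine-like. In that setting none of the 4 genes passed in enteroendocrine-like cells (Cd74 at log2 -0.45, H2-Aa at -0.81, H2-Eb1 at -0.75 and H2-Ab1 at -0.28, edgeR adjusted p 0.865 each), the list median there was -0.37, and Cd74 (-0.84, 0.997) and H2-Eb1 (-1.74, 0.436) did not pass in tuft-like cells. With doublets at a common score left out, H2-Aa (log2 -0.98, edgeR adjusted p 0.208), H2-Eb1 (-1.0, 0.198) and H2-Ab1 (-0.41, 0.427) did not pass in enteroendocrine-like cells. H2-Eb1 in tuft-like cells did not with at most 10% mitochondrial UMIs (log2 -1.37, edgeR adjusted p 0.100).

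Stem-like cells had more transcripts of Reg1 and of Rbm3 in 2D, and fewer histone and mitochondrially encoded transcripts. The Reg3 lectins were higher too but did not pass over all genes. Reg1, a secreted lectin (ENSMUSG00000059654, chromosome 6, 78422711 to 78428667), rose from 16.9 ± 3.35 to 46.1 ± 5.62 CPM (SD, n = 2; edgeR adjusted p 0.0425). Rbm3, a cold-inducible RNA-binding protein (ENSMUSG00000031167, chromosome X, 8138975 to 8145880), rose from 275 ± 5.21 to 507 ± 55.3 CPM (SD, n = 2; edgeR adjusted p 0.0381). The histone genes Hist1h2ab (log2 -1.33 ± 0.13 SE), Hist1h4d (-0.85 ± 0.09 SE) and Hist1h4h (-0.79 ± 0.09 SE) fell, and so did mt-Atp8, an ATP synthase subunit (188 ± 8.15 to 103 ± 2.67 CPM, SD, n = 2; edgeR adjusted p 0.0381). The antimicrobial defence list rose, with 8 of 10 members above 0 and a median of 0.89. Reg3b was at 447 ± 226 and 2222 ± 2.20 CPM and Reg3g at 238 ± 72.3 and 859 ± 271 CPM (SD, n = 2), both antibacterial lectins. Reg1 and Reg3b were also among the markers used to name enterocyte-like clusters, and carry-over of enterocyte RNA into stem-like cells was not tested for them. In enterocyte-like cells Reg1 was at 1243, 1073, 285 and 900 CPM in 0D-1, 0D-2, 2D-1 and 2D-2. ER stress genes rose (16 of 16 above 0, median 0.28), with Herpud1 at log2 0.58 ± 0.08 and Xbp1 at 0.60 ± 0.09 (SE). Mitochondrially encoded genes fell (12 of 13 below 0, median -0.20), with mt-Nd4l at log2 -0.51 ± 0.07 and mt-Nd6 at -0.72 ± 0.10 (SE). For these lists camera's adjusted p was 2.62e-09 for both rising lists and 2.36e-12 for the mitochondrial list, and adjusted p = 0.590 with an estimated correlation for each. Adjusted over the list alone, 5 antimicrobial genes rose and 1 fell, 5 ER stress genes rose and 6 mitochondrial genes fell, against 0, 0 and 1 over all genes. Stem cell markers themselves were slightly higher (13 of 14 above 0, median 0.16, camera adjusted p 0.000395, and adjusted p = 0.753 with an estimated correlation), led by Rgmb at log2 0.51 ± 0.11 (SE). That call was lost without 0D-2 (median 0.09, camera adjusted p 0.0594) and without 2D-2 (0.09, 0.235), and the median was 0.26 without 0D-1 or without 2D-1 and 0.10 with at most 10% mitochondrial UMIs.

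In stem-like cells 7 of 11936 genes passed (2 higher, 5 lower, 1 of them an unnamed ribosomal RNA-like locus), 1434 had an unadjusted p under 0.05, and DESeq2 called 82. Without 0D-1, 0D-2, 2D-1 and 2D-2 the counts were 3, 2, 558 and 932. Without 0D-1, Hist1h4d (log2 -0.95, edgeR adjusted p 0.0849), Hist1h4h (-0.87, 0.138), Rbm3 (0.86, 0.189) and mt-Atp8 (-0.92, 0.0849) missed the threshold. Without 0D-2, Hist1h2ab (log2 -1.15, edgeR adjusted p 0.0647), Hist1h4d (-0.75, 0.158), Hist1h4h (-0.71, 0.201), Rbm3 (0.90, 0.153), Reg1 (1.25, 0.0929) and mt-Atp8 (-0.83, 0.122) did. With at most 10% mitochondrial UMIs Rbm3 (log2 0.85, edgeR adjusted p 0.0533) and the 3 histone genes (adjusted p 0.0658 to 0.0841) missed it, as the histone genes did with automatic doublet calls left out (0.0900 to 0.141) and at Leiden resolution 0.5 (0.0649 to 0.163). Ranges did not overlap for 44.6% of genes, against 33.3% for libraries that vary alike. Of the 30 lists tested, 13 passed, 7 higher and 6 lower. The antimicrobial median was 0.52 without 2D-1. Stem-like cells had 6287861 to 18352528 UMIs per library.

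Transit-amplifying-like cells had more Tifa and fewer transcripts of absorptive enterocyte genes in 2D. Tifa, an adaptor that links bacterial sugar sensing to NF-kB (ENSMUSG00000046688, chromosome 3, 127789805 to 127832164), rose from 19.4 ± 1.32 to 50.9 ± 1.55 CPM (SD, n = 2; edgeR adjusted p 0.0256). Enterocyte markers fell (16 of 17 below 0, median -0.66), with sucrase-isomaltase (Sis) at 69.1 ± 7.15 and 42.9 ± 0.486 CPM (SD, n = 2). In the 6 classes other than enterocyte-like cells the medians of these markers ran from -0.66 to 0.41, 5 of them below 0, and the enterocyte-like share was 0.691 times as large in 2D. The class drew on different clusters in each group. Of its 1335, 1214, 929 and 795 cells in 0D-1, 0D-2, 2D-1 and 2D-2, 2 clusters with goblet as the second-best class held 237, 250, 234 and 248 and 109, 133, 180 and 189. Lipid absorption genes fell as well (15 of 17 below 0, median -0.41), among them the apolipoprotein gene Apoa1 at log2 -0.96 ± 0.16 and Mogat2, of triglyceride resynthesis, at -0.57 ± 0.10 (SE). ER stress genes rose (18 of 18 above 0, median 0.42), with the stress transcription factor gene Atf4 at log2 0.46 ± 0.09 and asparagine synthetase (Asns) at 0.69 ± 0.13 (SE). Fatty acid oxidation genes fell (15 of 16 below 0, median -0.30), with Creb3l3 at 11.2 ± 4.34 and 3.77 ± 0.740 CPM (SD, n = 2). Camera's adjusted p was 4.74e-14 for enterocyte markers and 3.67e-08 for lipid absorption, both with an adjusted p = 0.440 with an estimated correlation. For ER stress it was 3.67e-08 and for fatty acid oxidation 8.37e-05, both with an adjusted p = 0.664 with an estimated correlation. The fatty acid oxidation median was -0.19 without 0D-1, and the lipid absorption median -0.24 with at most 10% mitochondrial UMIs and -0.18 with automatic doublet calls left out. Adjusted over the list alone, 12 enterocyte, 8 lipid absorption and 1 fatty acid oxidation genes fell and 8 ER stress genes rose, against 0 over all genes in each list.

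In this class 1 of 12323 genes passed, 2337 had an unadjusted p under 0.05 and DESeq2 called 347. No gene passed in edgeR without 0D-1 or without 0D-2, 1709 did without 2D-1 and 1090 without 2D-2; Tifa then had a log2 change of 1.46 (edgeR adjusted p 0.817) without 0D-1 and 1.33 (0.303) without 0D-2. Tifa also missed the threshold with at most 10% mitochondrial UMIs (log2 1.27, edgeR adjusted p 0.0703) and at Leiden resolution 0.5 (0.92, 0.0766). Genes with the next smallest p, not passing, were Ern2, an ER stress sensor of mucous cells (40.1 ± 2.94 and 81.4 ± 3.07 CPM, SD, n = 2), the phospholipase gene Pla2g2f (3.73 ± 0.847 and 12.9 ± 0.704 CPM, SD, n = 2) and the histone genes Hist1h2ap (log2 -0.97 ± 0.09 SE) and Hist1h4h (-0.89 ± 0.08 SE). Of 31 lists, 14 passed, 5 higher and 9 lower. For 51.3% of genes the ranges did not overlap, against 33.3% for libraries that vary alike. Libraries held 11737524 to 23419403 UMIs of this class.

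In enterocyte-like cells the antimicrobial defence list was higher in 2D, with members going both ways and none passing over all genes. It rose (9 of 11 above 0, median 1.07), with Reg3b at 8214 ± 931 and 19493 ± 4974 CPM and Reg3g at 3399 ± 7.54 and 7141 ± 1510 CPM (SD, n = 2), while its member Reg3a was at 96.2 ± 4.26 and 59.4 ± 9.03 CPM (SD, n = 2). ER stress genes rose (16 of 16 above 0, median 0.32), with Herpud1 at log2 0.89 ± 0.11 and the chaperone gene Hspa5 at 0.53 ± 0.10 (SE). Fatty acid oxidation genes fell (16 of 17 below 0, median -0.36), with the lipid droplet gene Plin2 at log2 -0.45 ± 0.11 and Cpt1a at -0.34 ± 0.11 (SE). Of the 1059, 917, 942 and 410 enterocyte-like cells of 0D-1, 0D-2, 2D-1 and 2D-2, the cluster led by Fabp1, Reg1 and Rbp2, with Creb3l3 among its leading genes, held 264, 240, 16 and 49. For the 3 lists camera's adjusted p was 5.76e-06, 2.11e-08 and 1.41e-05, and adjusted p = 0.657, 0.395 and 0.657 with an estimated correlation. Among members, adjusted over the list alone, 6 antimicrobial genes rose and 1 fell and 7 ER stress genes rose, against 0 over all genes. Without 2D-1 the antimicrobial median was 0.56 and the fatty acid oxidation median -0.20. G2 and M phase genes had all 25 members above 0 (median 1.60, camera adjusted p 5.90e-09, and adjusted p = 0.657 with an estimated correlation), a rise that was lost without 2D-1 (median -0.05, camera adjusted p 0.702). The median was 1.02 with automatic doublet calls left out and 0.23 at Leiden resolution 0.5. Hmmr, a spindle gene, was at 8.86, 9.21, 54.7 and 11.4 CPM in 0D-1, 0D-2, 2D-1 and 2D-2, and 838 of the 942 enterocyte-like cells of 2D-1 lay in 1 cluster that held 23, 10 and 12 cells of the others.

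With edgeR 0 of 11665 genes passed in enterocyte-like cells, 1698 had an unadjusted p under 0.05 and DESeq2 called 93; without 2D-1 edgeR called 402 and without 2D-2 2643. The 5 genes with the smallest p, each with an edgeR adjusted p of 0.132, included Tifa (10.9 ± 1.75 and 36.7 ± 5.84 CPM, SD, n = 2), the retinal dehydrogenase gene Aldh1a1 (55.4 ± 7.51 and 23.2 ± 0.584 CPM, SD, n = 2) and the glutathione transferase gene Gstm3 (81.4 ± 0.719 and 43.8 ± 1.18 CPM, SD, n = 2). Of 30 lists, 16 passed, 8 each way. Ranges did not overlap for 47.1% of genes, against 33.3% for libraries that vary alike. This class had 5824888 to 21059389 UMIs per library.

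Paneth-like cells had lower levels of stem and mitotic transcripts and higher levels of enteroendocrine and tuft transcripts in 2D. Stem cell markers fell (14 of 14 below 0, median -0.60), with Olfm4 at 252 ± 46.0 and 118 ± 50.5 CPM and the Wnt receptor partner Lgr5 at 18.9 ± 0.523 and 12.9 ± 0.465 CPM (SD, n = 2). G2 and M phase genes fell (25 of 25 below 0, median -0.52), with the kinetochore gene Cenpf at log2 -0.86 ± 0.19 (SE). Enteroendocrine markers rose (13 of 15 above 0, median 1.15), with proglucagon (Gcg) at 3.56 ± 2.14 and 17.3 ± 1.44 CPM and Chga at 10.3 ± 0.962 and 21.8 ± 1.10 CPM (SD, n = 2), and tuft cell markers rose (9 of 9 above 0, median 1.22), from low levels such as 0.387 ± 0.154 CPM for Sh2d6, which reached 1.88 ± 0.191 CPM (SD, n = 2). Tuft markers had a median above 0 in all 6 classes other than tuft-like cells (0.14 to 1.22), goblet markers in all 6 others (0.12 to 0.58) and enteroendocrine markers in 5 of 6 (-0.10 to 1.15), while the shares of these classes were 1.33, 1.22 and 1.40 times as large in 2D. Stem markers had medians below 0 in 3 of the 6 classes other than stem-like cells (-0.60 to 0.12), while the stem-like share was 0.483 times as large. Carry-over of stem-like or transit-amplifying-like RNA into Paneth-like cells was not tested. The class's own markers lay near 0 (median -0.10, 10 of 13 below). Lysozyme (Lyz1) was at 48828 ± 1562 and 41694 ± 672 CPM (SD, n = 2). With camera the adjusted p was 4.15e-14 for stem, 8.87e-21 for G2 and M phase, 2.00e-26 for enteroendocrine and 3.39e-11 for tuft genes. In the same order it was adjusted p = 0.485, 0.485, 0.251 and 0.284 with an estimated correlation. For the class's own markers camera's adjusted p was 0.0458 (adjusted p = 0.485 with an estimated correlation). That call was lost without 0D-2 (median -0.06, camera adjusted p 0.439) and without 2D-2 (-0.08, 0.661), and the median was -0.16 without 0D-1 and -0.21 without 2D-1. It was lost as well with at most 10% mitochondrial UMIs (camera adjusted p 0.0907), with automatic doublet calls (0.131) or those at a common score (0.459) left out and at Leiden resolution 0.5 (0.0796). Without 0D-1 the G2 and M phase median was -0.32. With automatic doublet calls left out the stem median was -0.24 and the G2 and M phase median -0.28, and with those at a common score left out the G2 and M phase median was -0.83 and the tuft median 0.56. Of single members, adjusted over the list alone, 9 stem and 17 G2 and M phase genes fell and 8 enteroendocrine and 4 tuft genes rose, against 0 over all genes.

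Among 11321 genes tested in Paneth-like cells, edgeR called 0 (smallest adjusted p 0.0574), 807 had an unadjusted p under 0.05 and DESeq2 called 20. Without 0D-2 edgeR called 4, without 2D-1 85 and without 2D-2 361. Of 30 lists, 19 passed, 11 higher and 8 lower. Ranges did not overlap for 37.5% of genes, against 33.3% for libraries that vary alike. The class had 15069393 to 28269976 UMIs per library, and its median cell 26010, 14713, 23553 and 10059 UMIs in 0D-1, 0D-2, 2D-1 and 2D-2.

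Goblet-like cells had higher levels of clock and enteroendocrine genes in 2D. Circadian clock genes rose (11 of 13 above 0, median 0.20), with Nr1d2 at 6.69 ± 0.0730 and 13.4 ± 0.236 CPM, Nr1d1 at 17.7 ± 3.29 and 31.2 ± 4.81 CPM and Per3 at 3.16 ± 0.0619 and 4.82 ± 0.0144 CPM (SD, n = 2), genes of the negative arm of the clock. Enteroendocrine markers rose (12 of 15 above 0, median 0.88), with the incretin gene Gip at 9.87 ± 0.629 and 24.0 ± 5.17 CPM (SD, n = 2), and these markers had medians above 0 in 5 of the 6 classes other than enteroendocrine-like cells. Camera's adjusted p was 0.000157 and 1.92e-08, and adjusted p = 0.689 with an estimated correlation for both. The clock median was 0.36 without 0D-2 and 0.38 without 2D-2, and the enteroendocrine median 0.47 without 2D-1. Oxidative phosphorylation genes fell (26 of 27 below 0, median -0.24, camera adjusted p 0.000183, and adjusted p = 0.795 with an estimated correlation), with Ndufa1 at 177, 191, 81.8 and 140 CPM in 0D-1, 0D-2, 2D-1 and 2D-2. That call was lost without 2D-1 (median -0.01, camera adjusted p 0.347), and the median was -0.61 without 2D-2. When adjusted over the list alone, 2 clock and 4 enteroendocrine genes rose and 0 oxidative phosphorylation genes passed, against 0 over all genes.

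Of 12473 genes tested in goblet-like cells edgeR called 0 (smallest adjusted p 0.371), 957 had an unadjusted p under 0.05 and DESeq2 called 38. The edgeR counts were 29 without 0D-1, 39 without 0D-2, 1101 without 2D-1 and 5775 without 2D-2. The 5 genes with the smallest p, not passing, included Sval1 (39.7 ± 0.868 and 16.7 ± 1.79 CPM, SD, n = 2) and Cdk5rap1, a tRNA-modifying enzyme (5.13 ± 0.531 and 1.79 ± 0.192 CPM, SD, n = 2). Most goblet-like cells of 2D-1 (2092 of 2520) lay in the cluster led by Ddx60 and Irf7, which held 69, 81 and 225 cells of 0D-1, 0D-2 and 2D-2. Of 31 lists, 13 passed, 7 higher and 6 lower. For 45.9% of genes the ranges did not overlap, against 33.3% for libraries that vary alike. Libraries held 20362949 to 28475312 UMIs of this class.

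Enteroendocrine-like cells had fewer dividing-cell transcripts in 2D and more goblet and Paneth transcripts. G2 and M phase genes fell (25 of 25 below 0, median -0.76), with the proliferation antigen gene Mki67 at 128 ± 36.8 and 60.9 ± 6.41 CPM (SD, n = 2; edgeR adjusted p 0.0204) and Cenpf at 60.5 ± 18.4 and 26.6 ± 1.36 CPM (SD, n = 2; edgeR adjusted p 0.0204). Olfm4 fell from 429 ± 142 to 150 ± 59.7 CPM (SD, n = 2, edgeR adjusted p 0.0310). The histone genes Hist1h2ap (log2 -1.59 ± 0.24 SE) and Hist1h4d (-1.20 ± 0.11 SE) fell too. Olfm4 was among the markers used to name stem-like clusters, and Mki67 and Cenpf among those for transit-amplifying-like clusters. The shares of these classes were 0.483 and 0.669 times as large in 2D. Carry-over of their RNA into enteroendocrine-like cells was not tested. A cluster led by Ghrl and Neurog3 held 145, 151, 138 and 209 of the 564, 609, 759 and 922 cells of this class in 0D-1, 0D-2, 2D-1 and 2D-2. Goblet markers rose (11 of 11 above 0, median 0.58), with the mucin gene Muc2 at 830 ± 10.5 and 1429 ± 157 CPM (SD, n = 2; edgeR adjusted p 0.0353), and their medians lay above 0 in all 6 classes other than goblet-like cells. Clock genes rose (12 of 13 above 0, median 0.23), with Nr1d1 at 4.55 ± 0.423 and 9.90 ± 0.698 CPM (SD, n = 2). The 3 lists had a camera adjusted p of 2.58e-33, 1.25e-14 and 0.000199, and adjusted p = 0.415, 0.373 and 0.373 with an estimated correlation. Adjusted over the list alone, 23 G2 and M phase genes fell and 7 goblet and 2 clock genes rose, against 2, 1 and 0 over all genes. In all, 35 of 12149 genes passed with edgeR (18 higher, 17 lower), 1146 had an unadjusted p under 0.05 and DESeq2 called 33. Without 0D-2 the count was 118, without 2D-1 290 and without 2D-2 291. Without 0D-1, Cenpf (log2 -0.83, edgeR adjusted p 0.115), Mki67 (-0.74, 0.0627), Olfm4 (-1.13, 0.0948) and Muc2 (0.80, 0.360) missed the threshold, and Muc2 did without 0D-2 (0.76, 0.121). With at most 10% mitochondrial UMIs Cenpf, Mki67, Olfm4 and Muc2 missed it too (adjusted p 0.0539 to 0.0808). With automatic doublet calls left out the count was 8, while Mki67 (log2 -0.65, edgeR adjusted p 0.887), Cenpf (-1.26, 0.865), Olfm4 (-0.86, 0.871), Muc2 (1.67, 0.865), Hist1h2ap (-0.57, 0.871) and Hist1h4d (-1.17, 0.103) did not pass, and the goblet median was 1.41. With doublets at a common score left out Muc2 did not pass (log2 0.66, edgeR adjusted p 0.654) and the goblet median was 0.33, and DESeq2 did not call Olfm4 or Hist1h2ap. Of 30 lists, 17 passed, 8 higher and 9 lower, and 10 passed without 0D-1. Ranges did not overlap for 39.9% of genes, against 33.3% for libraries that vary alike, and the class had 4406512 to 6187922 UMIs per library.

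Tuft-like cells had lower levels of histone genes in 2D beside the MHC class II genes, and higher levels of Paneth transcripts and of colipase. Hist1h2ab fell from 31.4 ± 8.89 to 7.81 ± 0.504 CPM (SD, n = 2; edgeR adjusted p 0.0137) and Hist1h4d from 123 ± 21.8 to 61.9 ± 1.82 CPM (SD, n = 2; edgeR adjusted p 0.0334). The colipase gene Clps (chromosome 17, 28558149 to 28560766), a cofactor of lipases, rose from 23.1 ± 6.63 to 134 ± 16.0 CPM (SD, n = 2; edgeR adjusted p 0.000193). Clps was also among the leading genes of a Paneth-like cluster, beside Defa23, and in tuft-like cells it stood at 0.109%, 0.219%, 0.613% and 0.899% of its level per Paneth-like cell in 0D-1, 0D-2, 2D-1 and 2D-2. Its call was lost with automatic doublet calls left out (log2 2.07, edgeR adjusted p 0.0896) and with those at a common score left out (1.46, 0.0647). Tuft cell markers lay slightly above 0 (11 of 12, median 0.22, camera adjusted p 0.0147, and adjusted p = 0.645 with an estimated correlation), a call lost without 0D-1 (median 0.06, camera adjusted p 0.795), without 2D-2 (0.10, 0.362) and with automatic doublet calls left out (-0.03, 0.598). The median was 0.40 without 0D-2. Oxidative phosphorylation genes fell (27 of 27 below 0, median -0.30, camera adjusted p 6.44e-08, and adjusted p = 0.591 with an estimated correlation), with Ndufa1 at 187 ± 22.6 and 130 ± 12.0 CPM (SD, n = 2). The median was -0.16 without 0D-1 and with automatic doublet calls left out, and 0 members passed edgeR when adjusted over the list alone or over all genes. With edgeR 27 of 9903 genes passed (23 higher, 4 lower), 902 had an unadjusted p under 0.05 and DESeq2 called 20. The count was 103 without 2D-1, 168 without 2D-2 and 6 with automatic doublet calls left out. Without 0D-2, Hist1h2ab (log2 -1.68, edgeR adjusted p 0.0964) and Hist1h4d (-0.79, 0.220) missed the threshold. Hist1h4d did so with automatic doublet calls (-0.71, 0.997) or those at a common score (-0.80, 0.120) left out, and DESeq2 did not call it. Of 30 lists, 15 passed, 8 higher and 7 lower, and 10 passed without 2D-2. Ranges did not overlap for 41.6% of genes, against 33.3% for libraries that vary alike. This was the shallowest class, with 1447054 to 2319555 UMIs per library.

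Paneth cell marker transcripts were higher in 2D in every class other than Paneth-like cells. All 13 tested members lay above 0 in stem-like (median 0.73), transit-amplifying-like (1.13), enterocyte-like (1.16), enteroendocrine-like (1.42) and tuft-like cells (2.13), and 11 of 13 in goblet-like cells (1.02). In enteroendocrine-like cells the intelectin gene Itln1 rose from 359 ± 75.6 to 1263 ± 183 CPM (SD, n = 2; edgeR adjusted p 0.000721) and the alpha-defensin gene Defa22 (chromosome 8, 21162277 to 21163249) from 178 ± 26.4 to 622 ± 99.9 CPM (SD, n = 2; edgeR adjusted p 0.000562), and Defa34, Defa5, Defa21 and Defa20 rose too (log2 2.66, 1.74, 1.68 and 2.01). In tuft-like cells the ribonuclease gene Ang4 rose from 59.2 ± 16.8 to 254 ± 108 CPM (SD, n = 2; edgeR adjusted p 0.00478), and Defa3, Defa5, Defa29, Defa30 and Mptx2 rose (log2 2.71, 2.60, 2.33, 2.18 and 2.46). Without 0D-1, Defa30 in tuft-like cells missed the threshold (log2 1.83, edgeR adjusted p 0.106), and without 0D-2 Defa5 did (2.33, 0.0610). With automatic doublet calls left out, Itln1 (log2 1.71, edgeR adjusted p 0.538), Defa34 (2.22, 0.0858) and Defa20 (1.81, 0.156) in enteroendocrine-like cells and Defa3, Defa5, Defa30 and Mptx2 in tuft-like cells (adjusted p 0.0543 to 0.140) missed it. Defa20 did so with doublets at a common score left out (log2 1.39, edgeR adjusted p 0.224) and at Leiden resolution 0.5 (1.62, 0.0773), and Mptx2 with doublets at a common score left out (1.75, 0.0647). DESeq2 did not call Defa5 in either class or Defa3 and Mptx2 in tuft-like cells. Defa5 in tuft-like cells was at log2 1.69 without 2D-1, and the enteroendocrine-like list median was 0.94 without 0D-1. Over all genes, 7 markers passed in enteroendocrine-like, 11 in tuft-like and 0 in the other classes; adjusted over the list alone, 13, 13, 12 (stem-like), 12 (transit-amplifying-like), 13 (enterocyte-like) and 8 (goblet-like) passed. By class, camera's adjusted p was 5.34e-31, 1.66e-24, 4.52e-44, 2.27e-67, 8.90e-73 and 2.33e-15 in stem-like, transit-amplifying-like, enterocyte-like, enteroendocrine-like, tuft-like and goblet-like cells. In the same order it was adjusted p = 0.590, 0.440, 0.352, 0.373, 0.591 and 0.689 with an estimated correlation. These levels were small beside those of Paneth-like cells, whose own share was also higher in 2D. The median marker in stem-like cells stood at 0.162%, 0.271%, 0.396% and 0.544% of its level per Paneth-like cell in 0D-1, 0D-2, 2D-1 and 2D-2, and in tuft-like cells at 0.122%, 0.292%, 0.723% and 0.857%. The Paneth-like level itself differed, at 17604, 14596, 18558 and 9989 marker UMIs per cell in 0D-1, 0D-2, 2D-1 and 2D-2, which raises the percentages of 2D-2. Marker UMIs per goblet-like cell were 126, 155, 154 and 159, and per stem-like cell 28.9, 41.1, 72.4 and 50.9. Per 1000 UMIs of the class, goblet-like cells had 12.1, 12.7, 19.0 and 17.2 marker UMIs and stem-like cells 1.99, 2.51, 3.55 and 4.28.

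**Figure D3:**
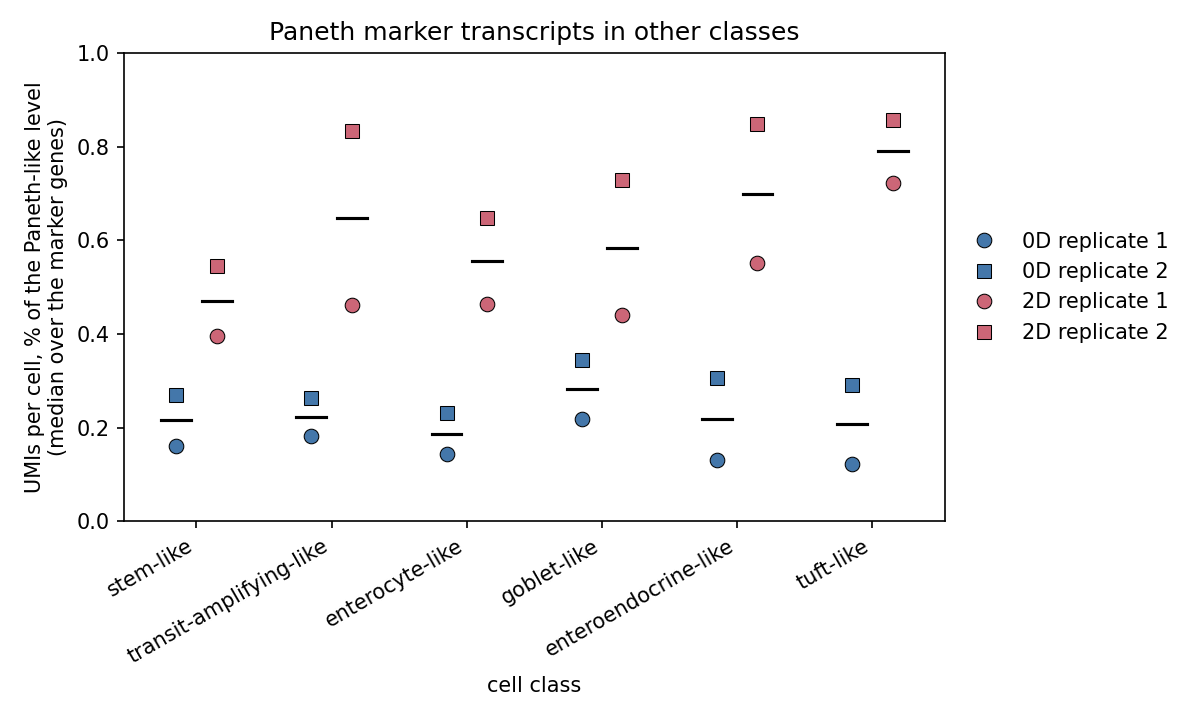
Paneth marker UMIs per cell as a percentage of the level in Paneth-like cells of the same library, as the median over 13 markers, for each other cell class (x axis) and library (points). All values lie between 0.122% and 0.857%, with both 2D libraries above both 0D libraries in each class.

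Lastly, the change in enterocyte-like cells was set against that in stem-like cells, as a test of the difference itself. Tifa rose more in enterocyte-like cells, by 1.12 ± 0.12 log2 units (SE; edgeR adjusted p 0.0281), going from 13.2 and 10.5 CPM in 0D to 44.4 and 33.9 CPM in 2D there and from 54.8 and 48.4 to 89.3 and 68.5 CPM in stem-like cells. Reg3a (chromosome 6, 78380709 to 78383827) differed by -1.92 ± 0.22 log2 units (SE, edgeR adjusted p 0.0372). In enterocyte-like cells it was at 107 and 101 CPM in 0D and 57.7 and 68.6 CPM in 2D. In stem-like cells it was low, at 1.61, 2.03, 3.70 and 4.73 CPM in 0D-1, 0D-2, 2D-1 and 2D-2. That class alone lay below the expression level of the naming rule, so the opposite direction there rests on low counts. Gcg, which lay below the expression level of the naming rule and is named after its values were seen, differed by 2.77 ± 0.29 log2 units (SE; edgeR adjusted p 0.0281). In stem-like cells it was at 12.3, 11.7, 5.52 and 1.18 CPM, and in enterocyte-like cells at 1.76, 2.17, 5.91 and 1.82 CPM. Of 12651 genes, 4 passed with edgeR, 1 of them an unnamed locus, with 2 in each direction. At an unadjusted p under 0.05 there were 1081, and DESeq2 called 6. With doublets at a common score left out edgeR called 0, with automatic doublet calls left out 19, with at most 10% mitochondrial UMIs 84 and without the low-count filter 447. Reg1, not passing, had a difference of -2.67 ± 0.35 log2 units (SE; edgeR adjusted p 0.0768). As to the classes compared, 838 of the 942 enterocyte-like cells of 2D-1 lay in a cluster that held 23, 10 and 12 cells of 0D-1, 0D-2 and 2D-2.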

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

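In this part, the test of damaged cells for the interferon genes and that of doublets for the Paneth genes were chosen before their results were seen, and the other tests were chosen only after the result was seen.

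Stem-like and enterocyte-like cells differed in their change from 0D to 2D for 4 of 12651 genes (edgeR's quasi-likelihood test of the difference itself, adjusted threshold 0.05), among them Tifa (1.12 ± 0.12 log2 units, SE), Reg3a (-1.92 ± 0.22) and Gcg (2.77 ± 0.29). DESeq2 called 6, and edgeR called 0 with doublets at a common score left out, 19 with automatic doublet calls left out, 84 with at most 10% mitochondrial UMIs and 447 without the low-count filter. No explanation was tested for this difference.

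Paneth cell marker transcripts were higher in 2D in all 6 other classes. Leaving out called doublets kept the list's call in each of these classes (medians 0.77 to 1.69), so called doublets were not its only source. The median stem-like cell held 1.58 times as many marker UMIs in 2D as in 0D, past the 1.5 set against doublets, but only through 2D-1. Its counts were 21, 29, 44 and 35 UMIs in 0D-1, 0D-2, 2D-1 and 2D-2, not scaled for depth. In all 6 classes the median cells of both 2D libraries lay above those of both 0D libraries, with 23, 33, 59 and 53 UMIs in transit-amplifying-like cells. In tuft-like cells the mean was 23.5, 52.7, 130 and 112 marker UMIs per cell in 0D-1, 0D-2, 2D-1 and 2D-2. The median there was 16, 26, 34 and 32. In enteroendocrine-like cells the means were 29.6, 48.8, 124 and 77.3 and the medians 17, 25, 38 and 31. The summed rise in these classes thus lay in part in cells far above the median. Doublets stay open, most of all there. The markers were also compared in stem-like, enterocyte-like, enteroendocrine-like and tuft-like cells. In each class at least 11 of the 13 lay within 2-fold of that class's median percentage of the Paneth-like level in every library. That goes against these cells making them in another mix than Paneth-like cells. It cannot tell free RNA or doublets from cells making all of them weakly in the Paneth mix. Free Paneth cell RNA in the droplets is consistent with that fixed mix and with class medians that differed by at most 1.8268-fold within any library, so the rise may follow the larger Paneth-like share in 2D. The marker calls in enteroendocrine-like and tuft-like cells may fall under this. So may Clps in tuft-like cells, at 0.753 to 1.05 times the markers' median percentage. Defa34 in enteroendocrine-like cells (0.368 to 1.32 times) and Defa5 in tuft-like cells (0.466 to 1.27) left the 2-fold range in a library. An effect of sleep deprivation on what any of the 6 classes makes stays open. The rise of goblet, enteroendocrine and tuft markers outside their classes stays open as untested.

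Interferon response genes were high in 2D-1 alone. Admixed cells of another type would by themselves leave some classes near 0, but the lowest of the 7 class medians in 2D-1 was 1.3059. That does not exclude such cells, since free RNA from them could reach droplets of every class, which was not tested. Leaving out cells over 10% mitochondrial UMIs left the median of 2D-1 at 1.71701, so the cells above that cut do not account for it by themselves. The goblet-like cluster led by Ddx60 and Irf7 had a median mitochondrial share of 9.66%, so much of it stayed in. Damaged cells under the cut, and RNA leaked from damaged cells, were not tested. An infection or another exposure of the animals behind that library, and a response to sleep deprivation in them alone, stay open as untested.

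Replication-dependent histone transcripts and the ribosomal RNA-like locus Gm42418 had lower fitted levels in 2D in all 7 classes (for the histones as a median), although in enterocyte-like cells of 2D-1 the histone median lay 0.05 log2 units above 0D. Fewer cells in S phase cannot account for Gm42418, which lay below the S phase median in stem-like and transit-amplifying-like cells of each 2D library, with -0.674821 log2 units as the gap nearest to 0. For the histone genes the gap nearest to 0 was -0.118503, within the margin set for that test, while the others were -0.53, -0.29 and -0.28, so S phase stays open for them in part. Both kinds of transcript mostly lack poly(A) tails, and a difference in library preparation between 0D and 2D may lower them in every class, as the signs show in 7 of 7, though by unequal amounts (histone medians from -0.15 to -0.84 and Gm42418 from -0.75 to -1.91). The labels do not say which libraries were prepared together, so preparation stays open beside sleep deprivation.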

How the results depend on the processing

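Only the removal of doublets at a common score was chosen after seeing the data. All other alternatives were planned. Keeping every cell in the main setting rested on a reading of the planned doublet rule, and leaving out the automatic calls follows the other reading. Of the values for class shares, 58 of 64 moved by less than the spread between libraries, of those for gene counts 43 of 102 stayed within 1.5 times, and of those for list counts 67 of 87. With 2 libraries per group, leaving 1 out cannot move a share difference by more than that spread, so those values counted as unmoved by arithmetic. The 64 also include the edgeR count of classes passing on cell numbers, which stayed at 0. For named genes, 4877 of 5965 values stayed on the same side of the threshold, 1008 came to pass it, 80 no longer passed and 0 changed direction while called. Changes of direction in genes called in neither fit were not counted apart and lie among the 4877. Of the 36 called named genes, 36 kept their call with RLE scaling, without the low-count filter and without 2D-1 or 2D-2. It was lost by 7 with DESeq2, 5 at Leiden resolution 0.5, 10 with at most 10% mitochondrial UMIs, 8 with doublets at a common score left out, 11 without 0D-1, 13 without 0D-2 and 26 of 35 with automatic doublet calls left out. The cause was not tested for any moved value below, except that leaving out a library leaves fewer libraries. Depth limits tuft-like cells most, at 1447054 to 2319555 UMIs per library, and medians of 9247.5 to 13340.5 UMIs per cell limit what a single cell shows.

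Gene counts under DESeq2 were 758 in all cells and 82, 347, 93, 20 and 38 in stem-like, transit-amplifying-like, enterocyte-like, Paneth-like and goblet-like cells. With no low-count filter they were 567 in stem-like, 683 in transit-amplifying-like, 29 in Paneth-like, 217 in goblet-like, 376 in enteroendocrine-like and 189 in tuft-like cells, and 447 for the difference between stem-like and enterocyte-like cells. With at most 10% mitochondrial UMIs they were 4 in stem-like, 0 in transit-amplifying-like, 29 in enterocyte-like, 1 in Paneth-like and 1 in goblet-like cells and 84 for the difference. With automatic doublet calls left out, from 3 libraries only, they were 9 in transit-amplifying-like, 8 in enteroendocrine-like and 6 in tuft-like cells and 19 for the difference. With doublets at a common score left out they were 13 in stem-like and 107 in transit-amplifying-like cells and 0 for the difference. At Leiden resolution 0.5 they were 13, 6 and 54 in stem-like, transit-amplifying-like and enteroendocrine-like cells. Counts of lists were 0 in all cells and in each of the 7 classes with an estimated correlation and with fry. In Paneth-like cells 10 lists passed with automatic doublet calls left out and 12 with those at a common score.

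Differences of shares in percentage points were -5.45 for stem-like and -8.66 for enterocyte-like cells at Leiden resolution 0.5. With at most 10% mitochondrial UMIs they were -3.78 for transit-amplifying-like, 0.855 for goblet-like and 4.51 for enteroendocrine-like cells, and with doublets at a common score left out -7.61 for transit-amplifying-like cells.

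Leaving out 1 library at a time, gene counts ran from 0 to 4045 in all cells, 2 to 932 in stem-like, 0 to 1709 in transit-amplifying-like, 0 to 2643 in enterocyte-like, 0 to 361 in Paneth-like, 29 to 5775 in goblet-like, 26 to 291 in enteroendocrine-like and 23 to 168 in tuft-like cells. Counts of lists ran from 12 to 21, 12 to 15, 13 to 15, 12 to 17, 14 to 21, 11 to 14, 10 to 18 and 10 to 17 in the same order. Differences of shares ran from -9.33 to -6.43 for stem-like, -7.37 to -4.09 for transit-amplifying-like, -8.29 to 0.00145 for enterocyte-like, 4.20 to 12.0 for Paneth-like, 5.31 to 8.24 for goblet-like, 2.64 to 3.74 for enteroendocrine-like and 0.408 to 1.98 for tuft-like cells. With a 2D library left out, the spread comes from the 0D pair and the lone 2D library is assumed to vary like it.

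The 2 groups share replicate numbers only in their titles. Deviations of same-numbered libraries correlated at 0.217 in all cells, -0.125 in stem-like, 0.0348 in transit-amplifying-like, -0.104 in enterocyte-like, 0.143 in Paneth-like, 0.165 in goblet-like, 0.0825 in enteroendocrine-like and -0.00915 in tuft-like cells, so with 2 pairs nothing shows that the numbers pair libraries. With the replicate number as a block, gene counts were 43 in stem-like, 324 in transit-amplifying-like, 240 in Paneth-like, 242 in goblet-like, 366 in enteroendocrine-like and 125 in tuft-like cells and 0 in all cells and enterocyte-like cells, and 16 lists passed in all cells.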

Other observations

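Slc15a2, a peptide transporter gene (ENSMUSG00000022899, chromosome 16, 36750177 to 36784962, protein-coding), was nearly absent from both 2D libraries. Over all cells it had 307, 204, 10 and 1 UMIs in 0D-1, 0D-2, 2D-1 and 2D-2 (log2 change -5.28 ± 0.54 SE, edgeR adjusted p 0.146). In enteroendocrine-like cells it had 21, 19, 1 and 0 UMIs and passed (log2 -5.37 ± 0.73 SE, edgeR adjusted p 0.0108), and in goblet-like cells it had 112, 66, 1 and 0. This gene, below the expression level of the naming rule, was chosen after its values were seen. The labels do not say whether the 0D and 2D mice were of the same strain and source, so a strain variant stays open as untested for this gene, and a difference in strain or source for the contrast of 0D with 2D.

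Rbm3 lay above 0 in all 7 classes, with log2 values of 0.88 in stem-like, 0.83 in transit-amplifying-like, 1.03 in enterocyte-like, 1.00 in Paneth-like, 0.62 in goblet-like, 0.64 in enteroendocrine-like and 0.55 in tuft-like cells, of which only that in stem-like cells passed with edgeR. Tifa did too, at 0.62, 1.39, 1.76, 0.52, 0.90, 0.73 and 0.47 in the same order, and passed in transit-amplifying-like cells only. Nr1d2 was at 1.00 ± 0.15 (SE) in goblet-like cells and at -0.03 ± 0.20 in stem-like and -0.02 ± 0.19 in Paneth-like cells, with the difference between classes not tested here. These genes were chosen for this account after their values were seen.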
